A study of Mus musculus with 6 samples.

How the data were processed

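ChIP-seq with an anti-MafG antibody was done on formaldehyde-fixed mouse embryonic fibroblasts expressing T-N1G, a tethered Nrf1-MafG heterodimer, after 4 h with vehicle or with 1.0 µM MG132, per the labels' protocols. The series has 6 libraries: 2 vehicle, 2 MG132 and 2 input libraries. Groups were taken from the treatment label and replicate numbers from the titles.

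The deposited files are one summit list per ChIP library, in BED form, with 1-bp intervals and no header. Column 5 is a −log10 p or q value made by the authors' peak caller. The submitters' processing notes name bcl2fastq 2.16.0.10, Bowtie2 2.2.9 and MACS2 2.1.4 and the genome build mm9. The command lines, the score threshold, the treatment of duplicate reads and the use of the input libraries as control are not given in the sources used here. All scores exceed 1.30, which is where a q value of 0.05 would lie, and the lowest was 1.34. Each deposited list belongs to one library, and whether any step pooled libraries is not given in the sources used here. Scores were used to rank or filter summits within a list and never to compare one list with another, because a score grows with the number of reads. A deeper or cleaner library gives more summits at the same threshold, so a difference in list length mixes binding with depth and enrichment. Read depth is unknown from these files.

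Positions were converted to 1-based coordinates of mm9. The gene table at hand is of GRCm38.p6, a different build: 13 chromosome 1 summits, added over the 4 lists, lie beyond the last gene of that chromosome in GRCm38.p6. No coordinate was carried from one build to the other. For this reason 3 planned analyses were not run: position relative to genes, overlap with fixed gene lists (such as proteasome subunits and antioxidant genes), none of which has a result here, and the Maf recognition motif at summits.

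Summits of different lists were matched when no more than 200 bp apart. Reproducible MG132 sites were pairs of summits, one from each MG132 list, that were each other's nearest within 200 bp. An overlap was the share of the summits of one list with a match in another, with an exact Clopper-Pearson 95% interval. Each was set against 1000 random placements, in which the second list was shifted around each chromosome by a random distance. The log2 number of summits was compared between groups with an exact two-sided permutation test. Ranks of shared and other summits were compared by the difference of median percentiles, with 100000 permutations over summits. The split over chromosomes was compared with a chi-square statistic and 10000 permutations of list labels. Clustering was the share of summits with another of the same list within 10 kb, against 1000 uniform placements with the same number per chromosome. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. The text names the 10 reproducible MG132 sites with the best mean percentile, up to 10 sites found in all 4 lists, and vehicle summits found in both vehicle lists but in neither MG132 list.

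The procedures were tested on simulated lists before use. With 3894 simulated summits of which 50% and 90% had a partner, 50.0% and 90.0% were recovered. With 20% of summits placed beside another, the excess over random placement was 18.6%, and with none so placed it was 0.597%. Partners and neighbours were placed inside the match and clustering distances, so their recovery was certain. It checks the coding alone and not the choice of distance. In the rank test, a shift of 20 percentiles came out as 24.0. With no true difference, 3% of rank tests over 323 simulated summits and 5% of chromosome tests over 10470 fell under 0.05. The simulated chromosome lists were few and were drawn independently of each other, whereas the MG132 lists share most sites of the shorter one. The rate of the chromosome test therefore does not carry over to the real lists. The rank simulations drew independent percentiles for fewer summits than the MG132 lists hold, so the rate of that test does not carry over either.

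The tests, the match distance and most alternatives were fixed before the data were examined. The alternatives were other match distances (50 and 1000 bp), score minimums of 5 and 10, merging of summits within 500 bp, equal list lengths, crossed replicate numbers, a replicate block, other clustering distances (2 and 50 kb) and leaving out each replicate. Vehicle lists were set against the MG132 list of the same replicate number, and the SD of the log2 ratio is that of the 2 within-number ratios. The permutation test of list lengths has no replicate block. Whether the numbers pair the libraries cannot be shown with 2 numbers.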

Results

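Binding of a tethered Nrf1-MafG heterodimer was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against MafG. Nrf1 is a cap'n'collar transcription factor that is kept low by degradation in unstressed cells, and MafG is a small Maf protein with which it binds DNA as a pair. In the form used here, called T-N1G, both partners are tethered to each other. It was expressed in mouse embryonic fibroblasts that lack the small Maf proteins MafF, MafG and MafK. Cells received either vehicle or 1.0 µM MG132, a peptide aldehyde that blocks the proteasome, for 4 h. There were 2 vehicle libraries, 2 MG132 libraries and 2 libraries of unprecipitated input chromatin. Each ChIP library has its own list of summits, the single base of highest enrichment within each called peak, and each summit carries a score on a −log10 scale that is the authors' own value for that peak. The numbers of sequenced reads are not in these lists, so the depth behind a summit is unknown, and the input libraries have no list analysed here. Nothing in the labels says whether the replicates came from separate cultures, so p-values between libraries speak for these libraries alone.

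The first comparison asked how many sites were detected with and without proteasome inhibition. Far more sites were called after MG132. The lists held 3894 and 6576 summits in MG132 replicates 1 and 2, against 24 and 828 in vehicle replicates 1 and 2. The ratio of geometric means was 35.9-fold, a difference of 5.17 ± 3.08 on the log2 scale (SD of the 2 within-number ratios, n = 2). Replicate 1 alone gave 162-fold and replicate 2 alone gave 7.94-fold, so the size of the difference rested on the short vehicle list of replicate 1. Both MG132 lists were longer than both vehicle lists, but 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333, which is the value obtained. The vehicle lists differed from each other by 34.5-fold in length and the MG132 lists by 1.69-fold.

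**Figure D1:**
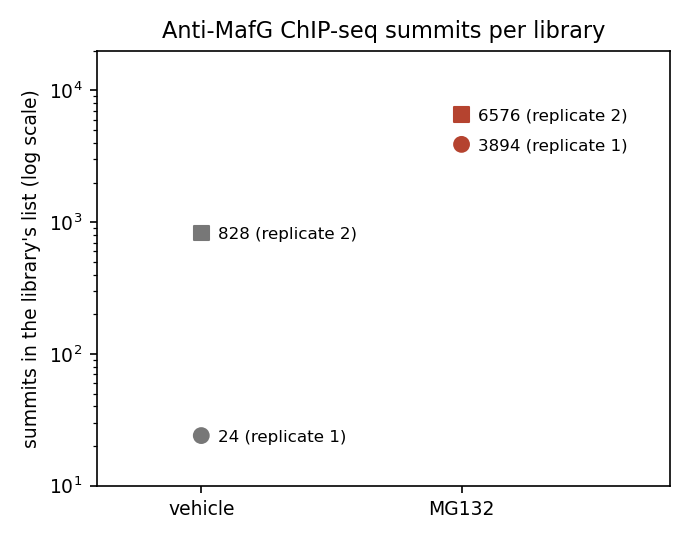
Number of called summits in each of the 4 ChIP libraries (vertical axis, log scale) for vehicle (grey) and MG132 (red); circles are replicate 1 and squares replicate 2. The MG132 libraries lie at 3894 and 6576 summits and the vehicle libraries at 24 and 828.

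The sites called after MG132 recurred between replicates at nearly the same base. Of the 3894 summits of MG132 replicate 1, 3379 (86.8%, exact 95% interval 85.7 to 87.8) lay within 200 bp of a summit of replicate 2, where random placement of the second list gave 0.110% on average and 0.308% at most. The placement p was 0.001 (one-sided), the smallest that 1000 placements can give, and it stayed there after Benjamini-Hochberg adjustment over the 4 overlaps tested. The shifts took no account of sequence to which reads cannot be mapped, here and in the overlaps below. The p therefore shows that the lists share positions, and not why they do. The median distance between matched summits was 14 bp, and 90% of them lay within 45 bp. Because the second list was longer, the same matches were 51.4% of its summits. All of these intervals cover counting error only, since neighbouring summits are not independent measurements.

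Recurrence followed the score. In MG132 replicate 1, 67.9% of the lowest 10% of summits by score were found in replicate 2, and 389 of 389 summits of the highest 10% were. In MG132 replicate 2, the share found in replicate 1 went from 13.1% among the lowest 10% of summits to 99.2% among the highest 10%. Across the 3379 reproducible sites, which were each other's nearest summits, the scores in the 2 lists had a Spearman rho of 0.65. That correlation is across sites within these libraries, and sites are not independent replicates.

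**Figure D2:**
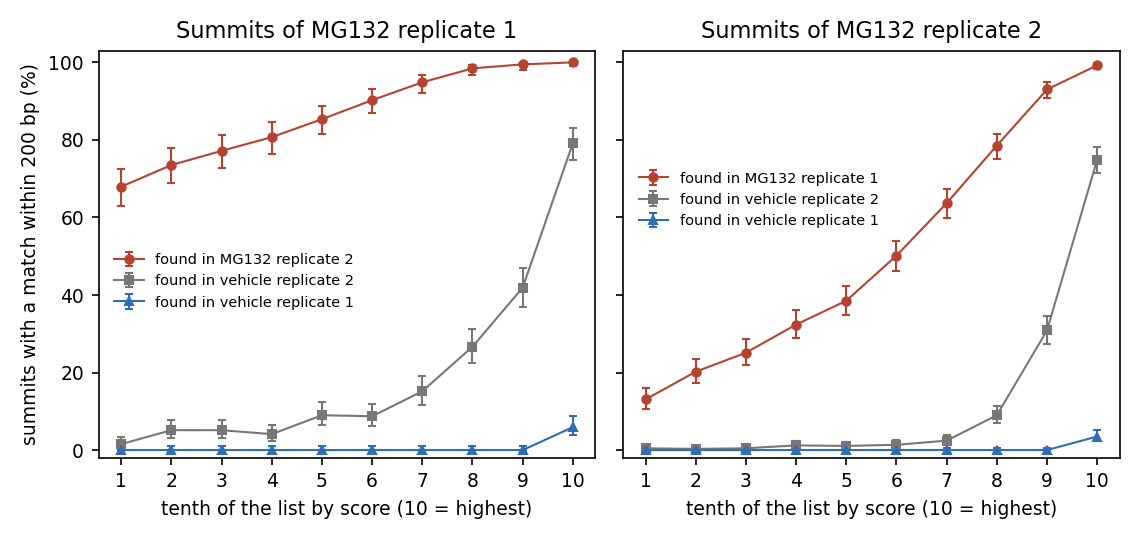
Percentage of summits of MG132 replicate 1 (left) and replicate 2 (right) that have a summit of another list within 200 bp (vertical axis), in 10 bins of the list ordered by score (horizontal axis, bin 10 highest); bars are exact 95% binomial intervals. The curves for the other MG132 list reach 100% and 99.2% in bin 10, the curves for vehicle replicate 2 reach 79.2% and 74.9%, and vehicle replicate 1 is matched in bin 10 alone, at 5.91% and 3.50%.

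The second comparison asked where the vehicle summits lay relative to the sites seen after MG132. Nearly all vehicle summits coincided with an MG132 summit. In replicate 1, 23 of 24 vehicle summits (95.8%, exact 95% interval 78.9 to 99.9) lay within 200 bp of a summit of the MG132 list, and in replicate 2, 802 of 828 did (96.9%, 95.4 to 97.9). Random placement gave 0.0625% and 0.106% on average, with a one-sided placement p of 0.001 in each case, the smallest attainable. Between the vehicle lists, 22 of the 24 summits of replicate 1 were found in replicate 2 (91.7%, 73.0 to 99.0), which is 2.66% (1.67 to 4.00) of the 828 summits of replicate 2. Conversely, of the 3379 reproducible MG132 sites, 763 (22.6%) were found in vehicle replicate 2 and 23 in vehicle replicate 1, and 2615 (77.4%) were in neither vehicle list. A site missing from a vehicle list was not called there. Whether it was unoccupied cannot be read from lists that give no signal below their threshold.

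The sites shared with vehicle mostly had high scores after MG132. The 23 summits of MG132 replicate 1 that matched vehicle replicate 1 had a median percentile of 99.5 within their list, against 50.1 for the other 3871 summits. The 802 summits of MG132 replicate 2 that matched vehicle replicate 2 had a median percentile of 92.8 (quartiles 86.1 and 96.6), against 45.0 for the other 5774. Both differences had a two-sided permutation p of 1e-05 over summits, which is the smallest that 100000 permutations can give and was the same after Benjamini-Hochberg adjustment over the 2 tests. Summits are not independent replicates, and a shorter list of the same sites would match mainly the strong summits of a longer one. Between the MG132 lists the share of replicate 2 found in replicate 1 also rose with score, from 13.1% to 99.2%. The test therefore does not bear on a difference between conditions. In MG132 replicate 2, the share of summits found in vehicle replicate 2 was 0.456% among the lowest 10% by score and 74.9% among the highest 10%. Of the 100 best reproducible MG132 sites by mean percentile, 97 were in vehicle replicate 2 and 22 in vehicle replicate 1.

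The best-ranked reproducible sites are named by their position in the mm9 mouse assembly, given as the summit of MG132 replicate 2. No mm9 gene annotation or sequence was used here, so their genes, exons or motifs are not stated. The first by mean percentile was on chromosome 6 at 31767831, ranked 2 of 3894 and 3 of 6576. It was followed by chromosome 9 at 119551225 (ranks 1 and 5), chromosome 13 at 51380250 (ranks 3 and 4), chromosome 4 at 14826103 (ranks 5 and 2) and chromosome 8 at 77613647 (ranks 4 and 7). The next was chromosome 1 at 195732078, ranked 6 in both lists. Chromosome 11 at 75197195 had ranks 9 and 1, and its score of 404 was the highest of MG132 replicate 2. Chromosome 3 at 107626369, chromosome 17 at 65033636 and chromosome 9 at 103573250 completed the first 10. Of these 10 sites, those on chromosome 13, on chromosome 17 and at 103573250 on chromosome 9 were not called in vehicle replicate 1, but all 3 were called in vehicle replicate 2.

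Altogether 22 sites were called in all 4 lists. The site on chromosome 8 at 77613647 was ranked 1 in both vehicle lists, with scores of 34.8 among 24 summits and 170 among 828. Its neighbour on chromosome 8 at 77607907, 5.74 kb away, was ranked 2 in both vehicle lists, 25 in MG132 replicate 1 and 45 in MG132 replicate 2. The site on chromosome 4 at 14826103 was ranked 4 and 3 in vehicle replicates 1 and 2, and that on chromosome 2 at 76546726 was ranked 5 and 4. By contrast, chromosome 9 at 119551225, which led MG132 replicate 1, was ranked 16 of 24 and 49 of 828 in vehicle. The sites on chromosome 9 at 122380880, chromosome 5 at 144175910 and chromosome 3 at 146318135 also belonged to the 10 best sites found in all 4 lists. Ranks from lists of such different lengths describe each list and do not measure a change at a site.

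The only vehicle summit that recurred between vehicle replicates without an MG132 summit within 200 bp lay beside the best MG132 site. On chromosome 6, vehicle replicate 1 had 2 summits 344 bp apart, at 31767497 and 31767841. Vehicle replicate 2 had its summit at 31767516, 19 bp from the first of these, with a score of 89.5. The MG132 summits lay at 31767829 and 31767831, which is 313 and 315 bp from the summit of vehicle replicate 2. The best MG132 site was therefore not counted as found in vehicle replicate 2, although a peak was called beside it.

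**Figure D3:**
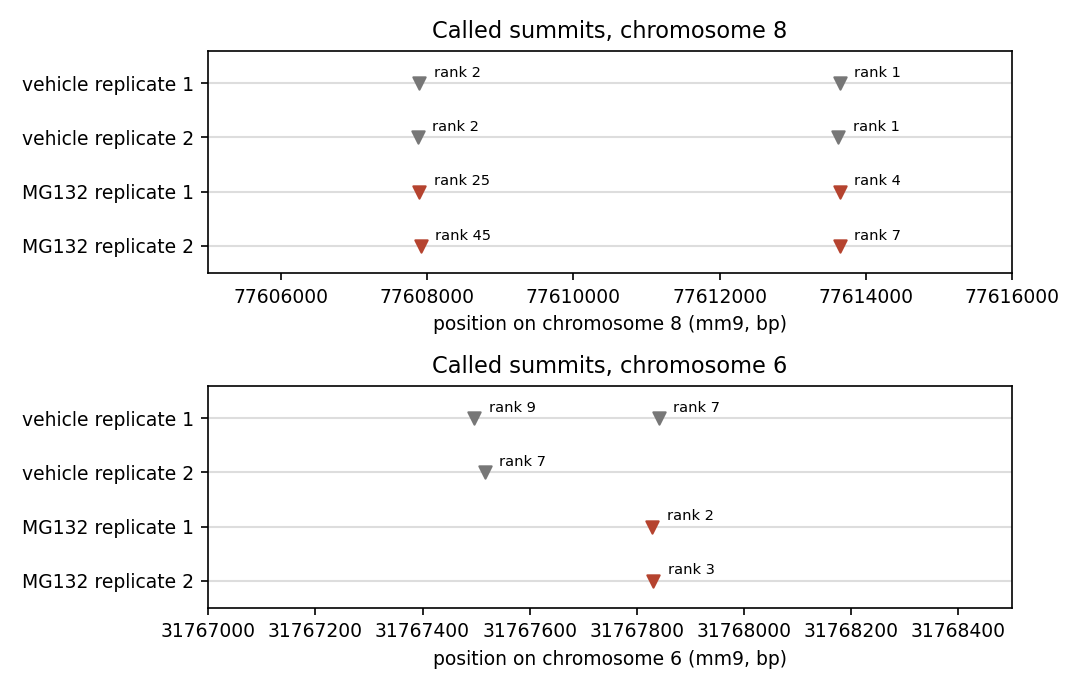
Called summits (triangles) of the 4 ChIP libraries, one row per library, along chromosome 8 (top) and chromosome 6 (bottom) in mm9 coordinates in bp; the number beside a triangle is its rank by score in its own list. On chromosome 8 both sites are called in all 4 libraries, and on chromosome 6 the summit of vehicle replicate 2 at 31767516 lies 315 bp from that of MG132 replicate 2.

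Summits were spread over chromosomes 1 to 19 and X, and no list had one on Y, on mitochondrial DNA or on unplaced sequence. Densities are per Mb between the chromosome's start and the last summit of any list. In MG132 replicate 2 the autosomes held between 1.83 (chromosome 14) and 3.79 (chromosome 19) summits per Mb, and X held 1.04. In MG132 replicate 1 the autosomes ranged from 0.908 (chromosome 14) to 2.36 (chromosome 19) per Mb, and X held 0.643. Relative to all autosomes together, the density on X was 0.418 (exact 95% interval 0.342 to 0.507) in MG132 replicate 1 and 0.400 (0.342 to 0.465) in replicate 2. It was 0.199 (0.0990 to 0.358) in vehicle replicate 2. Vehicle replicate 1 had no summit on X among 24, and the interval of its ratio, 0 to 2.46, is too wide to tell a low density from an even one. For the split over chromosomes, the chi-square statistic between the MG132 lists was 30.9 over 20 chromosomes (permutation p = 0.0444). The permutation treated summits as independent, although 3379 of the 3894 summits of replicate 1 had a match in replicate 2. Its p is therefore not calibrated, and whether the split differs between the lists is not settled. With scores of at least 5 only, which left 9455 of 10470 summits, the statistic was 28.3 and the permutation p = 0.0795. Per 1000 summits the statistic was 2.952 over all summits and 2.996 with that minimum. These figures are not effect sizes, because the part of the statistic due to sampling does not shrink with fewer summits.

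**Figure D4:**
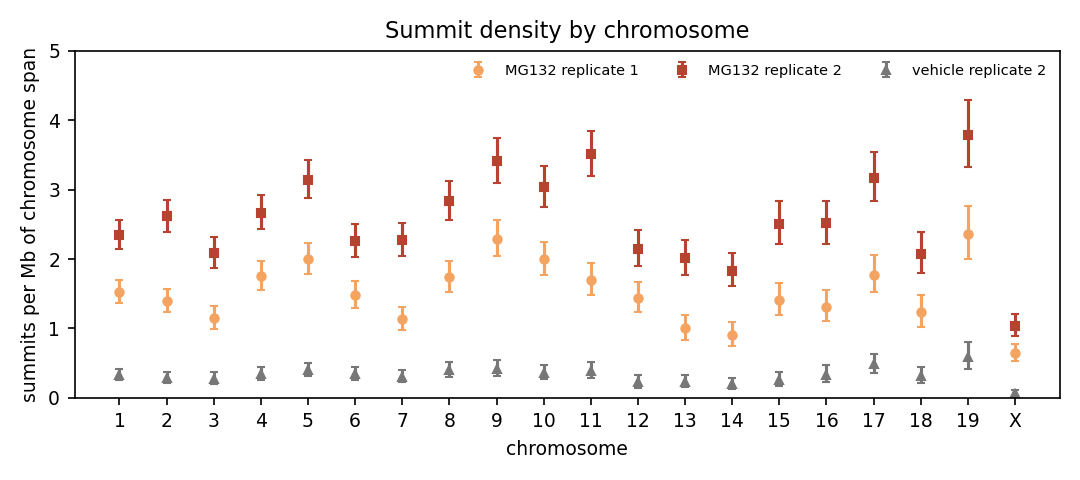
Called summits per Mb of chromosome span (vertical axis) by chromosome (horizontal axis) in MG132 replicate 1 (orange circles), MG132 replicate 2 (red squares) and vehicle replicate 2 (grey triangles); bars are exact 95% binomial intervals of each chromosome's share. X is the lowest chromosome in all 3 libraries shown, at 0.643, 1.04 and 0.0661 summits per Mb.

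Summits lay near one another more often than random placement gave, though most reproducible sites stood alone. Within 10 kb of another summit of the same list lay 240 of the 3894 summits of MG132 replicate 1 (6.16%, against 3.15% in random placements) and 817 of the 6576 of replicate 2 (12.4%, against 5.16%). The one-sided placement p was 0.001 in both tests, the smallest attainable, and the same after Benjamini-Hochberg adjustment over the 2. Random placement was uniform along each chromosome and took no account of sequence to which reads cannot be mapped. Joining reproducible MG132 sites no more than 10 kb apart left 3186 sites on their own, 93 groups of 2, 1 group of 3 and 1 group of 4. The groups named here were chosen after their values were seen. The group of 3 spanned 12689 bp on chromosome 9, from 118288374 to 118301062, with a best rank of 941 in MG132 replicate 2. The group of 4 spanned 7352 bp on X, from 166437849 to 166445200, with a best rank of 3265 in that list. Neither group had a summit in a vehicle list. The group of 2 with the best rank was the pair on chromosome 8 that was called in all 4 libraries.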

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

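The 3 alternatives chosen after seeing the data were MG132 lists cut to equal length, the overlap as a share of the longer list, and vehicle replicate 2 set against both MG132 lists. Of the 38 alternatives to results other than the summit numbers, 37 kept the direction and the side of the threshold. The exception was the split of MG132 summits over chromosomes, whose statistic was 28.3 (permutation p = 0.0795) with scores of at least 5, on fewer summits. Shares and the chi-square statistic cannot be negative, so among these results only the rank differences could have changed direction. The placement p was at its smallest value in every overlap and clustering alternative. A share could therefore fall far and still be counted as kept, so the ranges below say more than the tally. The other 7 alternatives kept the direction but have no test that 2 libraries a group could pass. The log2 ratio of MG132 to vehicle summit numbers (5.17) was 5.43 and 5.79 with scores of at least 5 and 10, 5.19 with close summits merged, and 2.99 without replicate 1 and 7.34 without replicate 2. The score minimums were the same for every list, so the ratios under them still carry any difference in depth. With the replicate number as a block the log2 ratio was 5.17 again, with a sign-flip p of 0.50, the smallest that 2 pairs can give. The replicate overlap of MG132 summits ranged from 51.4% (as a share of the longer list) to 87.3% (within 1000 bp) and was 71.1% with equal numbers of top summits. The share of vehicle summits found with MG132 ranged from 83.3% to 100% in replicate 1 and from 85.0% (within 50 bp) to 97.6% in replicate 2, and was 92.4% for vehicle replicate 2 in MG132 replicate 1. The difference in median percentile between shared and other MG132 summits (48.6) ranged from 46.3 to 49.4. The vehicle replicate overlap ranged from 83.3% (within 50 bp) to 100% (within 1000 bp), so vehicle replicate 1 summits unmatched within 200 bp had one of replicate 2 nearby. In MG132 replicates 1 and 2, clustering was 1.69% and 3.50% within 2 kb (0.636% and 1.06% in random placements). Within 50 kb it was 23.1% and 38.4% (14.7% and 23.1%), and with close summits merged 5.74% and 12.1% (3.15% and 5.16%). The planned tests of gene positions, gene lists and motifs and their alternatives were not run, for want of an mm9 reference. The unknown read depth limits every list length, and a vehicle list of 24 summits cannot show which of the weaker sites were occupied.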

Other observations

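The tests in this part, except that of the short vehicle list, were chosen after the results were seen. Summits called in MG132 replicate 2 and more than 1 kb from any summit of the other 3 lists included some of high score. The strongest lay on chromosome 6 at 52775772 (score 46.2, rank 596 of 6576), chromosome 1 at 129872611 (score 44.0, rank 633) and chromosome 5 at 77897654 (score 43.7, rank 654). In all, 3158 summits of MG132 replicate 2 (48.0%) and 514 of MG132 replicate 1 (13.2%) had no summit of another list within 200 bp, with median percentiles of 30.5 and 22.5 in their own lists. The best reproducible MG132 sites with no summit of either vehicle list within 200 bp were on chromosome 5 at 150779723 (ranks 72 and 99 in MG132 replicates 1 and 2) and chromosome 13 at 57119226 (ranks 97 and 81). The 4 sites grouped near the end of X had scores between 3.67 and 15.9 in the MG132 lists.

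The first pattern is the gap between vehicle lists of 24 and 828 summits. A candidate explanation is that the first is a less sensitive sampling of the same sites. The 22 summits of vehicle replicate 2 matched by replicate 1 had a median percentile of 98.7 in their list, and 20 of them were among its best 100, which is consistent with that explanation. Lower read depth, a less efficient precipitation and less of the heterodimer in the cells used for that library would all have this effect and were not separated here.

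The second pattern is the gap between vehicle and MG132 lists, for which a hypothesis is that both conditions rank the sites in one order and differ in sensitivity alone. Of the 82 top summits of vehicle replicate 2, 79 were among the 828 top summits of MG132 replicate 2. For MG132 replicate 1 it was 82 of 82, a difference of -3.66 percentage points, and this comparison list had no room to be higher. Of the 3 missed, 1 was the chromosome 6 summit, 315 bp from the best MG132 site. Another, on chromosome 10 at 11211942, was more than 1 kb from any MG132 summit. The last, on chromosome 17 at 4626276 (rank 62 of 828), had a summit of MG132 replicate 2 at 48 bp, but not among its 828 top summits. For 828 summits each, the shares were 68.8% for vehicle replicate 2 and 69.2% for MG132 replicate 1. Set against the 828 top summits of MG132 replicate 1, vehicle replicate 2 reached 59.4% and MG132 replicate 2 reached 69.2%. The shares of 69.2% compare the same pair of top lists from either side and are not separate benchmarks. The vehicle list was used whole, down to its lowest scores, while the MG132 lists were cut to their best summits. These shares compare single libraries whose lists hold many of the same sites, so no p-value is given and the hypothesis stays open, and more heterodimer after MG132 and a deeper library cannot be told apart from list lengths.

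The third pattern is the 24 summits of vehicle replicate 2 more than 200 bp from any MG132 summit. Of these, 5 (20.8%, exact interval 7.13 to 42.2) had one within 10 kb, which argues against too short a match distance for most of them and leaves it open for these 5. Leaving out the 4 within 1 kb, among them the summit on chromosome 6, left 20, a median of 101956 bp away. The highest scores were on chromosome 10 at 11211942 (32.8, rank 67 of 828), chromosome 5 at 147072666 (29.8) and chromosome 17 at 36368232 (24.99). Their median percentile of 63.4 (95% bootstrap interval 30.01 to 77.4) argues against calls near the score threshold for most of them, and 6 of the 20 lay below percentile 25, for which that stays open. Sites occupied in vehicle cells alone may account for them, but 0 of the 20 were in vehicle replicate 1, where 0.545 would be due at the rate of other summits, so that list is too short to tell. Artefacts of a single library, such as repeats, were not tested.

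The density of summits on X relative to the autosomes was 0.199 in vehicle replicate 2, 0.418 in MG132 replicate 1 and 0.400 in MG132 replicate 2, and the difference between them was not tested. No explanation of the low density was tested, since chromosome copy number, gene content and mappability were not used here.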
